A study of Rattus norvegicus with 6 samples.

How the data were processed

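RNA was measured in the endosalpinx, the mucosal lining of the oviduct, of 6 adult Sprague-Dawley rats, with 1 array for each animal. Per the labels, total RNA (0.3 µg per sample) was converted into a biotin-labelled sense target by a whole-transcript protocol and hybridised to Affymetrix arrays. The submitters' processing notes name RMA, which corrects background, normalizes quantiles and summarises probes, and Affymetrix Expression Console; no versions, batches or scan dates are given in the sources used here. The values the authors deposited are log2 signals, 1 per probe set and array, and were used as they stand. Their log2 scale was taken from the range of the values and from the named method. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed. RMA sets all arrays to a similar distribution, so a shift of most transcripts in 1 direction would not be visible, and it compresses changes of dim probe sets.

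The table held 29214 probe sets. In the annotation of the array, 15310 of them had exactly 1 gene symbol, 323 had several and 13581 had none listed. Of the probe sets with 1 symbol, 15279 had an Entrez identifier found in the RefSeq gene table of the rat assembly GRCr8, and 0 symbols needed an update through it. Probe sets with several symbols or none were left out, and for each gene the probe set with the highest mean over all arrays was kept, which left 14506 genes. The annotation does not mark control probe sets, so the alternative that used every probe set includes any controls among the unnamed ones. A family of odorant and pheromone receptor genes, used mainly by sensory neurons, served as a guide to background: a gene whose mean over all arrays lay at or below the 95th percentile of that family is described as within the receptor range. Depth has no meaning for arrays, and the number of arrays limits the precision.

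Mated and unmated rats were compared with limma (version 3.58.1 in R 4.3.3), by lmFit and eBayes without a trend, robust fitting or a block, on all 6 arrays. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. A looser count took genes with an unadjusted moderated p under 0.05 and a fold of at least 1.5, and is not corrected for the number of genes. Standard errors and 95% confidence intervals are those of the moderated fit, and SDs are those of the 3 arrays of a group. All tests were two-sided.

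A set of 36 gene lists, 20 of pathways and 16 of cell type markers, was written before the data were examined. Of their 675 entries 594 were measured, 6 of them under a newer symbol (Mt1, Cd59b, Bmal1, Ccn2, Ccn1 and Semg1), and the others are not analysed here. The lists on TNF and on retinoic acid were drawn up in the knowledge that the published study of these animals deals with both, so they are not independent evidence. Lists with at least 5 measured genes were tested with camera at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 35 lists that qualified; the list of uterine and endometrial gland genes had too few and was not tested. Beside it stand camera with a correlation estimated from these arrays, camera on ranks, and fry, which asks whether the genes of a list move on balance 1 way. With 6 arrays the estimated correlation is itself imprecise. Camera then also takes its test on the few residual degrees of freedom of these arrays, so it can hardly call a list.

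The named genes followed a rule written before the data were examined. As no gene passed the threshold, the rule took in each direction the 10 genes of smallest unadjusted p whose groups did not overlap. This means that all 3 mated values lay on 1 side of the 3 unmated values. Symbols that start with LOC, RGD or MGC, receptor family members and small RNAs were passed over. Olfactory receptor genes under their newer symbols, which start with Or, were passed over as well. The rule also took from each list the member of smallest unadjusted p. Genes named outside the rule are said to have been chosen after their values were seen.

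The procedure was tested on simulated arrays of independent normal noise with the means and moderated SDs of the real genes. Moderated SDs are drawn toward a common value and the arrays shared no structure, so recovery in the real data may be lower. With 200 genes changed among 14506, in 20 simulations of the comparison of mated and unmated rats, it recovered 89.6% of changes of 1.5-fold and 99.4% of changes of 2-fold, and 6.06% of its calls were false. With 10 changed genes it recovered 30.5% at 1.5-fold and 95% at 2-fold. A list shifted by 0.2 log2 units was called in 19 of 20 simulations, in which genes varied independently of each other.

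Alternatives written before the data were examined comprised the replicate number as a block, an intensity trend, robust fitting, array weights, a second quantile normalization, median centring, filters on the dimmest 25% and 50% of the genes, every probe set, averaged probe sets, each array left out, other thresholds and other list tests. Scripts used Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.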

Results

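The endosalpinx is the epithelial and stromal lining of the oviduct, where sperm and eggs meet. Its transcripts were measured on 6 arrays, 1 for each of 3 mated and 3 unmated rats, all killed at 0130 h of estrus. The mated females had joined a fertile male at 2200 h on the evening before, carried sperm or a vaginal plug when checked 30 min later, and were sampled 3 h after mating. The unmated females were housed alone. The comparison asks how mating changes gene expression in this tissue before ovulation. Only the mated rats had the company of a male, and a check at 30 min is described only for them. Effects of company and handling cannot be told apart from those of mating. The median log2 signal over all probe sets lay between 7.89 and 7.94 on the 6 arrays, and 10308 of the 14506 genes (71.1%) lay above the receptor range, whose upper limit was a log2 signal of 7.13. Epithelial transcripts chosen after their values were seen were bright in both groups. Krt8, a keratin of simple epithelia, averaged 12.92 ± 0.09 in unmated and 13.02 ± 0.10 in mated rats (SD, n = 3 per group), and Dnah11, a dynein of motile cilia, averaged 11.42 ± 0.06 and 11.32 ± 0.12.

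At 3 h after mating, the gene with the smallest p was Slpi-ps1, annotated as a pseudogene of the secretory leukocyte peptidase inhibitor. Its log2 signal was 8.74 ± 0.16 in unmated and 7.77 ± 0.27 in mated rats (SD, n = 3 per group). Slc5a3, which takes up the osmolyte myo-inositol, lay at 10.37 ± 0.16 in unmated and 11.01 ± 0.22 in mated rats. Of the gene lists, heat shock proteins were called higher in mated rats, with a median log2 fold change of 0.26 over 13 genes, and fibroblast markers were called lower, with a median of -0.085 over 12 genes. Both calls were lost with an estimated correlation (adjusted p = 0.582 with an estimated correlation for each list). No single gene passed the threshold, with a smallest adjusted p = 0.984 by limma over 14506 genes.

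At an unadjusted p under 0.05 there were 663 genes (4.57%), where chance alone would give 725.3, with 438 higher and 225 lower in mated rats. The split of directions moved with the scaling of the arrays. After a second quantile normalization 393 such genes were higher and 299 lower, and after centring each array on its median 336 were higher and 294 lower. The groups did not overlap for 1229 genes (8.47%), against the 10% that chance gives for 3 against 3. The 95% confidence interval of a log2 fold change reached 0.20 to either side of the estimate for the median gene, before any adjustment for the number of genes. A difference must be larger than this to pass the adjusted threshold: in simulations with 10 changed genes, 30.5% of 1.5-fold and 95% of 2-fold changes were recovered. These simulations used moderated SDs and independent noise, so recovery on the real arrays may be lower.

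**Figure D1:**
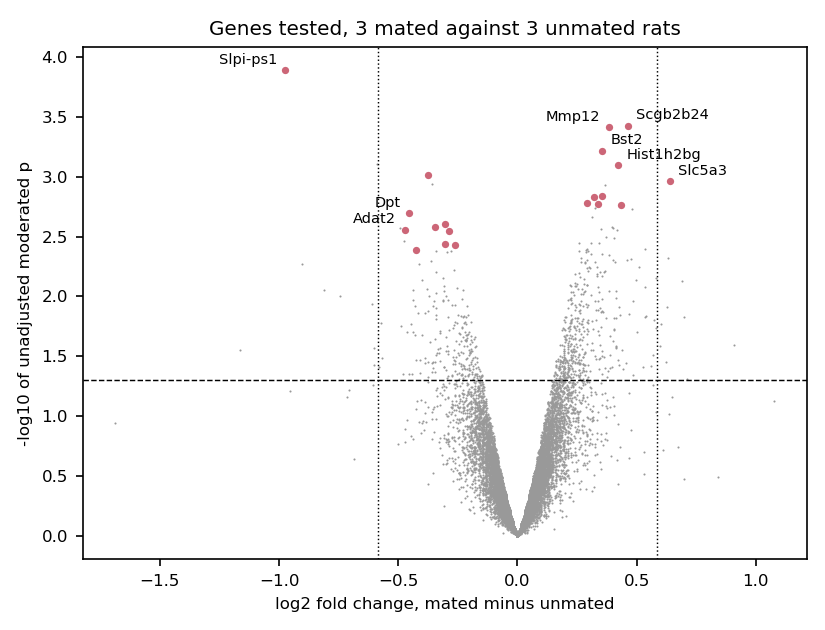
Log2 fold change of mated minus unmated rats on the x axis against -log10 of the unadjusted moderated p on the y axis, with 1 grey point for each of the 14506 genes and the 20 genes of the naming rule in red. The dashed line marks an unadjusted p of 0.05 and the dotted lines a fold of 1.5 either way; 19 genes lie beyond both, and no gene passes after adjustment.

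Among the 10 genes named as higher in mated rats, none of which passed the threshold (adjusted p = 0.984 for each by limma), Slc5a3 had the largest fold change, 0.64 on the log2 scale (95% confidence interval 0.34 to 0.94). Scgb2b24, a secretoglobin, differed by 0.46 (0.28 to 0.65), at a mean log2 signal of 4.37 that is within the receptor range. Mmp12, the macrophage metalloelastase, differed by 0.38 (0.23 to 0.53), and Bst2, the interferon-inducible antiviral protein tetherin, by 0.36 (0.21 to 0.51). Bst2 is bright, at 9.66 ± 0.05 in unmated and 10.02 ± 0.03 in mated rats (SD, n = 3 per group). Of the histone H2B genes, Hist1h2bg differed by 0.42 (0.24 to 0.61) and Hist1h2bq by 0.43 (0.22 to 0.65); members of this family are nearly identical in sequence, so which copy was measured is uncertain. The remaining genes were Zfp428, Pdzph1, Lipg, which encodes endothelial lipase, and Foxh1, a partner of Smad proteins, with log2 fold changes from 0.29 for Foxh1 to 0.36 for Zfp428, all 4 within the receptor range.

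Among the 10 genes named as lower in mated rats, again with none past the threshold (adjusted p = 0.984 for each by limma), Slpi-ps1 differed by -0.97 (95% confidence interval -1.30 to -0.65). Adat2, a subunit of a tRNA adenosine deaminase, differed by -0.47 (-0.73 to -0.22) and Dpt, the matrix protein dermatopontin, by -0.46 (-0.69 to -0.22). P2ry4, a nucleotide receptor, was at 10.20 ± 0.14 in unmated and 9.78 ± 0.16 in mated rats (SD, n = 3 per group), a difference of -0.43 (-0.67 to -0.18). Gucy1a2, a subunit of soluble guanylate cyclase, differed by -0.37 (-0.54 to -0.20) within the receptor range, and the kinase gene Rps6ka2 by -0.30 (-0.46 to -0.14). The other 4 were 6030498E09Rikl at -0.35, Lyc2, a lysozyme, at -0.30, Slc7a2, a transporter of cationic amino acids, at -0.29 and Zfp668 at -0.26; of these only Zfp668 lay above the receptor range.

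Slpi and Slpi-ps2, the latter chosen after its values were seen, lay higher in mated rats, opposite to Slpi-ps1. Slpi itself, an inhibitor of neutrophil proteases at mucosal surfaces, was at 12.49 ± 0.12 in unmated and 12.85 ± 0.15 in mated rats (SD, n = 3 per group), and Slpi-ps2 was at 7.97 ± 0.04 and 8.48 ± 0.30. These directions held under every scaling tried, none of the 3 genes passed the threshold, and near-identical copies can share signal on an array.

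**Figure D2:**
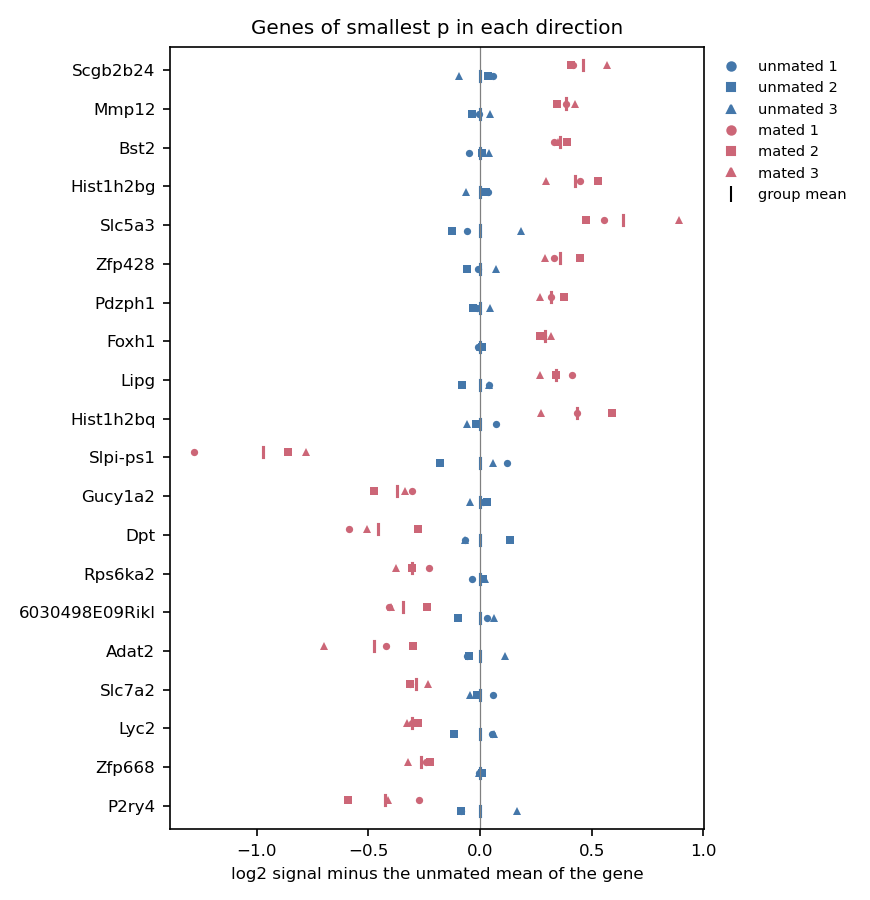
Log2 signal of the 20 named genes minus the mean of the 3 unmated arrays, 1 row for each gene, with 1 marker for each array (unmated in blue, mated in red) and a vertical bar at each group mean. The mated and unmated arrays do not overlap for any of these genes, which is how they were chosen, and Slpi-ps1 shows the widest gap, with a mean difference of -0.97.

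At an unadjusted p under 0.05 and at least 1.5-fold there were 19 genes, listed here after their values were seen. The 10 that were higher in mated rats included 4 solute carriers, namely Slc5a3, Slc26a4, which encodes the anion exchanger pendrin, Slc6a14, an amino acid transporter, and Slc16a3, a monocarboxylate transporter. The others were Chst10 at 0.91, Ceacam1 at 0.71, Or4k48b at 0.70, Amy1 at 0.63, the small heat shock protein Hspb1 at 0.62, and the peptidase neprilysin, Mme, at 0.60. The 9 that were lower were Oas1e at -1.16, Slpi-ps1, Prim1, a subunit of DNA primase, at -0.90, the RNA processing genes Alyref at -0.81 and Snrpd1 at -0.74, Serpinb9 at -0.61, Abca8a and Tmem45b, both at -0.60, and Or6c2b at -0.59. Of the 19, 4 lay within the receptor range, namely Amy1, Abca8a, Or4k48b and Or6c2b, and the last 2 belong to the receptor family that serves as the guide to background. This count was 42 without unmated replicate 3, 39 without mated replicate 1 and 30 without mated replicate 2, of which 14, 12 and 14 were among the 19. Without unmated replicate 2, mated replicate 3 or unmated replicate 1 it was 18, 27 and 27, of which only 8, 10 and 11 were among the 19. It was 34 with array weights and 9 with the dimmest 50% of the genes left out.

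Inflammatory lists gave no call. In the list of TNF and NF-kB response genes, 19 of 24 measured genes were higher in mated rats, or 16 after median centring, with a median log2 fold change of 0.05 (adjusted p = 0.0567 by camera), though 0 passed over all genes or adjusted over the list alone. Nfkb2, which encodes an NF-kB subunit, had the smallest p, at 9.53 ± 0.12 in unmated and 9.78 ± 0.13 in mated rats (SD, n = 3 per group). Tnf itself and Ptgs2, the inducible cyclooxygenase, were chosen after their values were seen; Tnf differed by 0.13 (95% confidence interval -0.08 to 0.34) within the receptor range, and Ptgs2 by 0.25 (-0.06 to 0.57). The components of TNF signalling had an adjusted p = 0.72, and Tab1, which activates the kinase Map3k7, had the smallest p at a log2 fold change of -0.15. These lists are not independent evidence, having been drawn up with the published study in mind. The TNF and NF-kB response list was called under 4 of 17 alternatives, among them without unmated replicate 1 (adjusted p = 0.00444) and without mated replicate 3 (adjusted p = 0.0416), over a range from 0.00444 to 0.582.

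The other defence lists were not called either. Cytokines and chemokines had an adjusted p = 0.455, led by Cxcl17, a mucosal chemokine, at 0.28 (95% confidence interval 0.10 to 0.46). Complement and epithelial defence genes had an adjusted p = 0.357, and 3 of 18 were higher at an unadjusted p under 0.05, with Slpi at the smallest p. The complement component C3, also in that list and the member of smallest p in the estrogen list, was at 9.26 ± 0.19 in unmated and 9.75 ± 0.27 in mated rats (SD, n = 3 per group), and its log2 fold change was 0.49 (0.15 to 0.83). Interferon response genes had an adjusted p = 0.733, led by Mx1, an antiviral GTPase, at 0.34 (0.07 to 0.62). The first 2 of these lists were each called under 1 of 17 alternatives, the removal of the dimmest 50% of the genes (adjusted p = 0.0118 and 0.0216).

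Retinoid and steroid lists gave no call either. Of 23 measured genes of retinoic acid synthesis and response, 12 were higher and 11 lower in mated rats (adjusted p = 0.791 by camera); the median was 0.02 as deposited and lay at or below 0 under the other scalings. Dhrs3, which reduces retinaldehyde to retinol, had the smallest p of that list, at 10.80 ± 0.33 in unmated and 10.42 ± 0.15 in mated rats (SD, n = 3 per group). Estrogen metabolism and response genes had an adjusted p = 0.55. In the glucocorticoid response list 16 of 20 genes were higher (adjusted p = 0.0567), led by Ddit4, an inhibitor of mTOR signalling, at 0.29 (95% confidence interval 0.10 to 0.48). That list was called without unmated replicate 1 (adjusted p = 0.000874) and without mated replicate 2 (adjusted p = 0.014), within a range from 0.000874 to 0.627 over 17 alternatives.

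Immediate early genes, which respond first to many stimuli, were higher in mated rats for 22 of 24 measured members under each of the 3 scalings. Their median log2 fold change was 0.07 and the list missed the threshold (adjusted p = 0.0567 by camera; adjusted p = 0.582 with an estimated correlation). Nr4a3, an orphan nuclear receptor, differed by 0.31 (95% confidence interval 0.05 to 0.57), and Fos, chosen after its values were seen, by 0.17 (0.01 to 0.34). The list was called under 7 of 17 alternatives, among them without unmated replicate 1 (adjusted p = 0.00105) and without mated replicate 2 (adjusted p = 0.00166). Circadian clock genes had an adjusted p = 0.0902, led by Bmal1, the core activator of the clock, at 0.22 (0.03 to 0.41), and were called without the same arrays (adjusted p = 0.000874 and 0.0207).

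Stress lists were led by heat shock proteins, molecular chaperones of which 12 of 13 measured genes were higher in mated rats (adjusted p = 0.000115 by camera). The call was lost with an estimated correlation (adjusted p = 0.582 with an estimated correlation), under which no list was called. The estimated correlation between these genes was 0.793. Neither over all genes nor adjusted over the list alone did any member pass; Hspd1, the mitochondrial chaperonin, had the smallest p at 0.34 (95% confidence interval 0.07 to 0.60), and Hspb1 was at 11.39 ± 0.47 in unmated and 12.02 ± 0.34 in mated rats (SD, n = 3 per group). The mean of the list relative to the unmated mean was 0.12, 0.12 and 0.43 on the 3 mated arrays and -0.15, 0.17 and -0.02 on the 3 unmated arrays. Without mated replicate 3 the call ended (adjusted p = 0.0958, median 0.11), within a range from 2.75e-10 to 0.582 over 17 alternatives. The unfolded protein response had an adjusted p = 0.136, led by Trib3 at 0.30. Antioxidant genes had an adjusted p = 0.091, led by Hmox1, the inducible heme oxygenase, at 6.86 ± 0.10 in unmated and 7.27 ± 0.19 in mated rats, within the receptor range, and were called without mated replicate 2 (adjusted p = 0.0125).

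**Figure D3:**
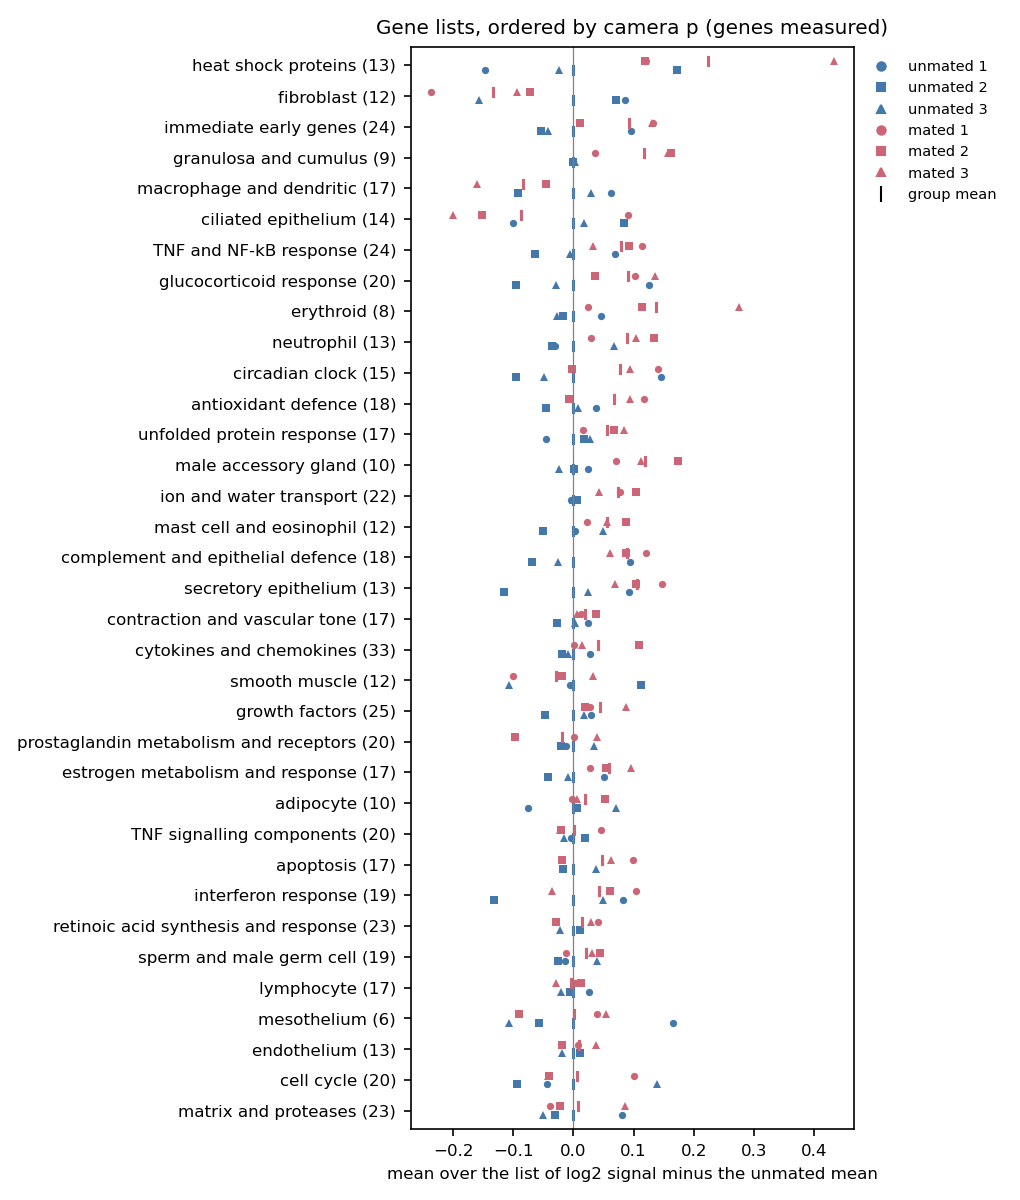
Mean over each gene list of the log2 signal minus the mean of the 3 unmated arrays, for the 35 lists tested, ordered by the camera p with the number of genes measured in parentheses, with 1 marker for each array (unmated in blue, mated in red) and a bar at each group mean. Heat shock proteins differ most, by 0.22 on average, and the mated and unmated arrays of that list overlap.

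Lists of transport, contraction and tissue turnover were not called in the values as deposited. Ion and water transport genes had an adjusted p = 0.344, led by Slc26a4, at 10.26 ± 0.12 in unmated and 10.89 ± 0.35 in mated rats (SD, n = 3 per group), and were called under 1 of 17 alternatives, the removal of the dimmest 25% of the genes (adjusted p = 0.0448). Genes of contraction and vascular tone had an adjusted p = 0.39, led by the gap junction gene Gja1 at -0.46 (95% confidence interval -0.83 to -0.10). Prostaglandin genes had an adjusted p = 0.527, led by the synthase Ptgds at -0.16, and matrix and protease genes had an adjusted p = 0.994, led by the gelatinase Mmp9 at 0.14. Growth factors had an adjusted p = 0.527, led by Bmp2 at 0.40, cell cycle genes an adjusted p = 0.87, led by thymidylate synthase, Tyms, at -0.30, and apoptosis genes an adjusted p = 0.733, led by Pmaip1 at 0.40. Mmp9, Bmp2 and Pmaip1 lay within the receptor range. In the lists of prostaglandin, TNF signalling, matrix, cell cycle, endothelial and mesothelial genes the median was slightly above 0 while the test pointed lower. For lymphocytes the mean was not of the same sign as the median and the test.

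Markers of stromal and epithelial cells were tested in the same way. Of the 12 measured fibroblast markers 11 were lower in mated rats as deposited and 9 after a second quantile normalization (adjusted p = 0.0139 by camera as deposited). This call was also lost with an estimated correlation (adjusted p = 0.582 with an estimated correlation), under which no list was called. Dpt passed when adjusted over the list alone (adjusted p = 0.0243) though not over all genes; Dcn, chosen after its values were seen, encodes decorin and was at 7.62 ± 0.48 in unmated and 7.27 ± 0.10 in mated rats (SD, n = 3 per group). The call ended without unmated replicate 1 (adjusted p = 0.117), unmated replicate 2 (adjusted p = 0.0922) or mated replicate 1 (adjusted p = 0.387) and with array weights (adjusted p = 0.0576), over a range from 9.48e-05 to 0.582. Ciliated cell markers were lower for 13 of 14 genes, at a median of -0.11 (adjusted p = 0.0567), and Spag6, the member of smallest p, was the exception at 0.17. The first principal component of the arrays, with 30.9% of the variance, placed mated replicate 1 at 12.9 and the other mated arrays at -11.0 and -10.9, and the mean of the ciliated list was 0.09 on the former and -0.15 and -0.20 on the latter. The unmated arrays did not follow this order, with components of 3.59, 8.25 and -2.89 and ciliated means of -0.10, 0.08 and 0.02. Without mated replicate 1 the ciliated list was called (adjusted p = 0.000491), and so it was without unmated replicate 1 (adjusted p = 0.00224), within a range from 0.000491 to 0.728. Secretory epithelium had an adjusted p = 0.357, led by Muc1 at 0.19, smooth muscle an adjusted p = 0.455, led by Lmod1, endothelium an adjusted p = 0.87, led by the receptor Tie1 at 0.33, mesothelium an adjusted p = 0.87, led by Wt1, and adipocytes an adjusted p = 0.664, led by Cfd.

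No list of blood cell markers was called in the values as deposited. Within the receptor range lay 12 of 13 neutrophil, 12 of 17 lymphocyte, 9 of 12 mast cell and eosinophil and 5 of 8 erythroid markers. Only 3 of 17 macrophage and dendritic markers lay there. For the other lists the counts and the absence of a call rest mostly on signals close to background. Macrophage and dendritic markers were lower for 13 of 17 genes (adjusted p = 0.0567), led by the class II gene RT1-Da, whose polymorphic family makes its signal uncertain, and were called without unmated replicate 2 (adjusted p = 0.00198) and without mated replicate 2 (adjusted p = 0.044). Neutrophil markers were higher for 10 of 13 genes (adjusted p = 0.0827) as deposited, 8 after median centring and 7 after a second quantile normalization, led by the elastase gene Elane at 0.22 within the receptor range, and were called without unmated replicate 3 (adjusted p = 0.0304). Lymphocyte markers, led by Lck, had an adjusted p = 0.87, and mast cell and eosinophil markers, led by Fcer1a, an adjusted p = 0.352. Erythroid markers had an adjusted p = 0.0803 by camera. Hemgn passed when adjusted over the list alone (adjusted p = 0.0173 by limma), without regard to the number of lists, and not over all genes. Its signal was 6.22 ± 0.07 in unmated and 6.53 ± 0.05 in mated rats (SD, n = 3 per group), within the receptor range.

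Lists of semen and ovary transcripts were not called in the values as deposited. Most of their genes were dim: 12 of 19 sperm, 9 of 10 male accessory gland and 6 of 9 granulosa and cumulus genes lay within the receptor range. Markers of sperm and male germ cells had an adjusted p = 0.792, with 11 of 19 genes higher in mated rats, and the member of smallest p, the transition protein gene Tnp1, was lower at -0.18 (95% confidence interval -0.34 to -0.02) within the receptor range. Male accessory gland genes had an adjusted p = 0.182, led by probasin, Pbsn, at 4.99 ± 0.19 in unmated and 5.31 ± 0.07 in mated rats (SD, n = 3 per group), also within the receptor range. Granulosa and cumulus markers were higher for 8 of 9 genes under each scaling at a median of 0.13 (adjusted p = 0.0567), led by Amh at 0.17 (-0.01 to 0.35). That list was called under 2 of 15 alternatives, among them camera on ranks (adjusted p = 0.0375), within a range from 0.0375 to 0.582.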

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

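All alternatives were chosen before the data were examined. No gene passed the adjusted threshold under any of 18 alternatives, whose smallest adjusted p ran from 0.104, without mated replicate 1, to 0.998. Among these alternatives, the added condition of 1.5-fold could not yield a gene, and the looser threshold of 0.1 used the main fit. Of the log2 fold changes of 80 named genes, 1136 of 1139 values kept their sign and 0 crossed the threshold. The exception was Angpt1, at 0.15 as deposited, -0.11 with array weights and -1.12 to 0.81 with 1 array left out. Many of the 80 genes were chosen for a small p or for groups that do not overlap. Such groups keep their direction when 1 array is left out, so the kept signs are no measure of robustness. The count at 1.5-fold and an unadjusted p under 0.05, 19 as reported, was 34 with array weights, 9 without the dimmest 50% of the genes, 63 over every probe set, 1 at 2-fold and 18 to 42 with 1 array left out. The lists called, 2 as reported, numbered 10 without the dimmest 25% of the genes, 9 without the dimmest 50%, 6 with camera on ranks, 0 with an estimated correlation, 0 with fry, and 2 to 7 with 1 array left out. The median of the heat shock list ran from 0.11 to 0.39 with 1 array left out, and its adjusted p was 0.582 with an estimated correlation. The median of the fibroblast list ran from -0.13 to -0.039 with 1 array left out and was -0.051 with array weights; its adjusted p was 0.582 with an estimated correlation, and without the dimmest 50% it had too few genes for a test. The lost calls with an estimated correlation cannot be put down to that correlation alone. Some lists had a larger p with it although their estimated correlation lay below the preset 0.01. For male accessory gland genes, at an estimated correlation of -0.0503, the unadjusted p by camera went from 0.0728 to 0.134. Not every such list had a larger p, as the retinoic acid list did not. Camera with an estimated correlation also takes its test on the few residual degrees of freedom of the 6 arrays, which raises small p-values whatever the correlation. Under it the smallest unadjusted p of any list was 0.0554 by camera, for granulosa and cumulus markers. The lost calls therefore say little about those lists. The cause of the other shifts was not tested.

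The labels give no pairing of the animals by replicate number. Same-numbered arrays deviated from their group means with correlations of 0.0035, -0.083 and 0.074 across genes. Not every array correlated best with its own number. Such small correlations show no strong shared deviation but cannot exclude a pairing. With the number as a block, 24 genes passed 1.5-fold and 4 lists were called. Signals within the receptor range, where 28.9% of the genes lie, are close to background and limit what can be said of them.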

Other observations

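The 3 patterns below and the question on solute carriers came from the results, so their tests were chosen after these were seen; those on the ciliated share, on the variation of the heat shock list and on other splits for the heat shock and fibroblast lists were chosen after the values they measure were seen as well. Some large differences rested on single animals. Pp2d1, with the largest fold difference of all genes at -1.69 (95% confidence interval -3.88 to 0.51), read 5.77 on mated array 2 and 9.24 to 10.77 on the other 5. Fndc7, at 1.08 (-0.14 to 2.29), read 8.87 on unmated array 2 and 10.93 to 11.64 elsewhere. Angpt1, a vascular growth factor, read 5.66 on unmated array 3 and 8.09 to 9.53 elsewhere. Oas1e, an oligoadenylate synthetase family gene, did not rest on 1 animal: it read 8.08 to 8.17 on the unmated arrays and 7.05, 5.89 and 7.99 on the mated arrays, which varied widely. These genes were chosen after their values were seen, and none passed the threshold.

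The first pattern is these large differences between animals of 1 group, followed over all genes by the SD within groups. If noise of dim probe sets were the main cause, over 50% of the most variable genes would lie within the receptor range. Of the 145 genes with the highest SD within groups, the top 1%, 26.9% lay there (39 genes, Clopper-Pearson interval 19.9 to 34.9). Among all genes 28.9% did, so the most variable genes were not enriched in genes of dim mean. This cannot exclude noise at background, since the range rests on the mean over 6 arrays and RMA compresses changes of dim probe sets. Pp2d1 read 5.77 on mated array 2 and Angpt1 5.66 on unmated array 3, near the receptor family medians of those arrays, 5.75 and 5.69. Fndc7, at 8.87 on unmated array 2, lay above the receptor range. Sequence variants between outbred animals may alter the binding of probes: 1 of the 145 was an RT1 histocompatibility gene, of 35 measured (p = 0.297 by Fisher's exact test), which is too few to decide. A biological difference between animals stays open and was not tested.

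The second pattern is a division of the arrays that does not follow mating. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The split of unmated 1, unmated 2 and mated 1 from the other arrays gave 1908 genes at an unadjusted p under 0.05. This was the highest count of the 10 splits, against 663 for the real split. No gene passed the adjusted threshold in this split (smallest adjusted p = 0.153 by limma). A structure of the samples is thus possible but not established. After a second quantile normalization the split still gave 1373, more than the 1229 of the next highest split before it. The signal distributions are therefore not the whole cause. A different share of ciliated cells may contribute to this split. The ciliated list was lower in unmated 3, mated 2 and mated 3, at a median of -0.15 (adjusted p = 0.0374 by camera). With an estimated correlation the list did not pass (adjusted p = 0.868 by camera), but that test could hardly have called it. The list mean on unmated 1 (-0.10) lay below that on unmated 3 (0.02), against the split. Secretory and neutrophil lists pointed higher on that side of the split without passing (adjusted p = 0.0902 and 0.0684 by camera). Crossed labels of mated 1 and unmated 3 cannot be told apart from correct ones. The 8 genes of the semen lists above the receptor range differed by only 0.086 ± 0.135 (SE) between the other mated and unmated arrays. They therefore do not mark mating. These genes were kept for a bright mean over all arrays, which favours genes that unmated rats express too. Mme among them averaged 12.13 in the unmated rats.

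The third pattern is the heat shock list, called higher in mated rats at the preset correlation. The call was lost with an estimated correlation (adjusted p = 0.582 with an estimated correlation), under which no list was called. Variation of the list between animals of 1 group is a candidate explanation, since the list mean ranged over 0.32 among the unmated and 0.31 among the mated arrays while the groups differed by 0.22. Of the 10 splits, 3, the real split included, gave as small an adjusted p as the real 0.000115, with 1.58e-09 the smallest among the others. An effect of mating stays open, and 10 splits cannot give a share under 0.05.

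The other counts were set against the same 10 splits, with the same limit, and each number of splits below includes the real split. With 0 genes past the adjusted threshold in the real split, all 10 splits meet that count by construction, which says nothing about chance; the highest other gave 1. At 1.5-fold and an unadjusted p under 0.05, 8 splits gave at least the real 19, and the highest other gave 38. For gene lists called, 8 splits gave at least the real 2, and the highest other gave 6. For the fibroblast list 3 splits gave as small an adjusted p as the real 0.0139, with 2.89e-05 the smallest among the others.

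Because 4 of the 10 genes higher by 1.5-fold at an unadjusted p under 0.05 were solute carriers, a shift of solute carrier genes with mating was tested as a hypothesis. Over 315 measured Slc genes, those 4 included, camera gave an unadjusted p of 0.31 at the preset and 0.418 at an estimated correlation, which leaves the hypothesis open. The mean log2 fold change was 0.028 over these genes and 0.010 over all others.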
